A study of Mus musculus with 73 samples.

How the data were processed

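The series concerns the histone variant H3.3 in early mouse development and holds 73 samples. The 8 RNA-seq libraries were used. The other 65 samples, 27 of H3.3 ChIP-seq, 27 inputs and 11 of CUT&RUN, were not analysed here. The RNA came from embryos kept in KSOM medium, and libraries were made from total RNA with a stranded SMART-seq kit, per the labels. The submitters' processing notes name Bowtie2, Trim Galore, SAMtools, HISAT2 and featureCounts without versions or roles, and the genome build mm10. The annotation and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes are uncertain.

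The authors deposited FPKM values (counted fragments per kilobase of gene, scaled to a common total of fragments per library), per the file headers, with 1 column per library and 25220 gene symbols, and every column was used. Columns named for 8-cell embryos with no treatment were taken as the EGFP 8-cell libraries, because the labels name no other 8-cell RNA-seq group without p150DN, and replicate numbers are those of the labels. FPKM fixes the sum of fragments per library, so a rise of some genes lowers the values of the others, and a change in total RNA per embryo cannot be seen. Of the symbols, 24920 (98.8%) matched a RefSeq gene table of assembly GRCm38.p6, the assembly of mm10, from which coordinates were taken.

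Sequencing depth was recovered from the values. In each library FPKM was multiplied by gene length for short RNA genes, and the most frequent product was taken as the worth of 1 fragment. Between 47 and 119 genes per library held that product. Whole fragments followed for 23312 of the 23316 genes above 0, within a tolerance of 0.02 fragments. Counted fragments were 20823283, 20229002 and 19337577 in EGFP 8-cell, 20374198, 19559765 and 16578221 in p150DN 8-cell, and 19361805 and 22488477 in EGFP blastocyst replicates. A gene of 1 kb at 1 FPKM therefore rests on about 20 fragments in each library. Genes under 300 bases, 416 tested for p150DN and 517 between the stages, rest on fewer, so these are called uncertain. The 74 and 209 of them that passed stay in the counts of changed genes. Replicates of a group correlated with r of 0.957 to 0.984 on the log2 scale, and their fragments differed by chi-square values per gene of 17.9 to 56, beyond counting noise, so each library counted as 1 replicate.

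The tests and lists were fixed before the data were examined. limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) was run on log2(FPKM + 1), two-sided, on genes of at least 1 FPKM in at least 3 libraries (p150DN against EGFP 8-cell embryos) or at least 2 libraries (EGFP blastocysts against EGFP 8-cell embryos), with the libraries of the compared groups only. Benjamini-Hochberg adjusted p-values below 0.05 were called. A count test was not used because the values are FPKM. Of 27 gene lists (884 genes), 23 had at least 5 tested members in each comparison and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The camera test with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. Ranges of a list's adjusted p over the alternatives are at the preset correlation. At the preset correlation 12 lists passed for p150DN and 10 for the stages, and each of these calls was lost with an estimated correlation. Between the stages the estimates for the 2-cell, junction and glycolysis lists (-0.011, -0.017 and -0.037) lay below the preset value. Their unadjusted camera p still rose, for the 2-cell list from 3.02e-09 to 0.00731. The loss of these calls therefore cannot be put down to a higher correlation between their genes. For p150DN the estimate for the G2 and mitosis list equalled the preset value (0.01), and its unadjusted camera p still rose, from 0.0296 to 0.0942. A call lost with an estimated correlation is therefore not by itself a sign that the genes of the list are correlated. None of the 15 mitochondrially encoded genes was found among the symbols, so that list gave no value.

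Genes were named by a fixed rule: Chaf1a and 14 further genes whatever their test, the 12 largest rises and falls among called genes with a mean of at least 5 FPKM and groups that did not overlap, and up to 4 called members per list. Symbols of predicted or unnamed genes were left out, which set aside 183 and 542 called genes in the 2 comparisons. Uchl1 and the genes given as above or below both stages were named after their values were seen.

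The fold changes of the 2 comparisons were correlated across genes, with 100 simulations of unchanged groups against the same EGFP 8-cell libraries. The pipeline was tested on simulated data with 200 changed genes. For p150DN against EGFP 8-cell embryos (10901 genes) it recovered 9.4% of genes changed 1.5-fold, 73% of those changed 2-fold and 100% of those changed 4-fold. For the stages (11072 genes) these shares were 27.6%, 83.6% and 98.4%. False calls were 12.8% and 10.5% of all calls, and 13 of the 17 and all 15 of them were genes under 300 bases (3.3% and 0% of calls among longer genes). Of 200 random lists, 1% and 0.5% had a camera p below 0.05. The simulated genes were drawn independently, while the estimated correlation of the real lists reached 0.502 and 0.578 (ribosomal protein genes). These shares therefore do not show that camera at the preset correlation is reliable for the real lists.

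The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, scaling by median of ratios, quantiles or TPM (also without the 100 most abundant genes), all 8 libraries in 1 fit, no trend, array weights, the replicate number as a block, and each library left out. Chosen after seeing the data were limma voom on the recovered fragments, genes of at least 300 bases, both p150DN replicates 2 and 3 left out, TPM scaling for the correlation, and a comparison of p150DN 8-cell embryos with EGFP blastocysts. Other computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.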

Results

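Gene expression was measured by RNA-seq in mouse embryos of a hybrid C57BL/6 / C3H background. There were 3 libraries of EGFP 8-cell embryos, 3 of p150DN 8-cell embryos and 2 of EGFP blastocysts. p150 is the large subunit of chromatin assembly factor 1 (CAF-1), the complex that places histone H3-H4 on newly replicated DNA, and is encoded by Chaf1a. The name p150DN stands for a dominant-negative form of it, and EGFP embryos served as the control. Between 16578221 and 22488477 fragments were counted per library, so that 1 FPKM in a gene of 1 kb corresponds to 16.6 to 22.5 fragments. Between 17310 and 18402 genes lay above 0 FPKM in the EGFP 8-cell libraries, 18991 and 18547 in the blastocyst libraries, and 18412, 20465 and 21282 in p150DN replicates 1, 2 and 3. The labels do not say that the replicates came from separate cultures or litters, so p-values measure the spread between these libraries, which may be technical. Fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes.

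Chaf1a (chromosome 17, 56040416 to 56068026, mm10) was first examined in every library. It stood at 165, 254 and 238 FPKM in the p150DN libraries and at 27.7, 30.2 and 28.8 FPKM in the EGFP 8-cell libraries. The blastocyst libraries held 26.5 and 27.2 FPKM. Chaf1a was higher in p150DN embryos by a log2 fold change of 2.86 ± 0.17 (SE; limma, adjusted p = 5.5e-05), and each p150DN library lay above each EGFP library. A gene-level value does not separate transcripts of the embryo's own gene from those of an introduced p150 sequence. Chaf1b, which encodes the p60 subunit of CAF-1 and lies on chromosome 16, was at 22.6 ± 0.527 FPKM in p150DN and 20.4 ± 1.83 FPKM in EGFP 8-cell embryos (SD, n = 3 each; log2 fold change 0.15, limma adjusted p = 0.41).

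**Figure D1:**
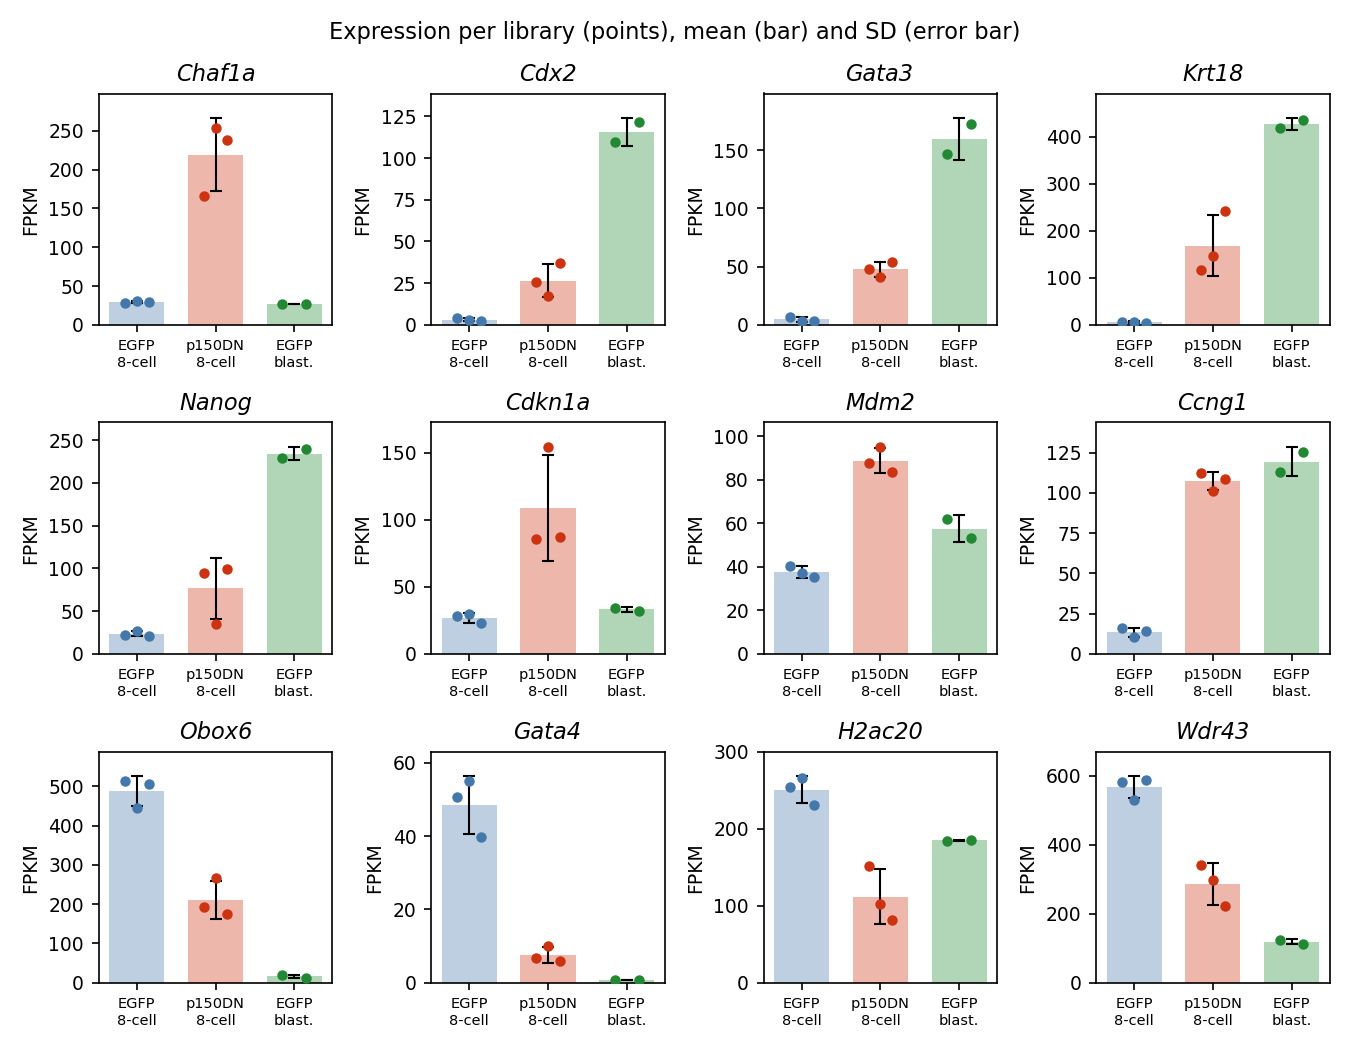
FPKM of 12 genes in EGFP 8-cell (blue), p150DN 8-cell (red) and EGFP blastocyst (green) libraries, with points for libraries, bars for group means and error bars for the SD. Chaf1a is at 165 to 254 FPKM in the p150DN libraries and at 26.5 to 30.2 FPKM in the others, the p150DN means of Cdx2, Gata3, Krt18 and Nanog lie between those of the EGFP groups, and Cdkn1a and Mdm2 have their highest mean in p150DN embryos.

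The comparison of p150DN with EGFP 8-cell embryos asked which transcripts differ between these groups at this stage. Whether CAF-1 function was disturbed was not measured here. Krt18 and Lrp2, both of the trophectoderm list, the outer layer of the blastocyst, were among the 12 largest rises. Krt18, a keratin of simple epithelia (chromosome 15, 102028216 to 102032026), was at 168 ± 64.7 FPKM in p150DN and 5.98 ± 1.4 FPKM in EGFP embryos (SD, n = 3 each; log2 fold change 4.56 ± 0.26 SE). The epithelial transcription factor gene Elf3 (chromosome 1, 135253574 to 135258472) rose from 2.24 ± 2.06 to 85.8 ± 6.17 FPKM (log2 fold change 4.92 ± 0.37), and Sdc4, a cell surface proteoglycan gene, from 3.63 ± 0.362 to 110 ± 7.81 FPKM (4.59 ± 0.14). Among the largest falls were Gata4 (chromosome 14, 63198914 to 63271712), from 48.4 ± 7.86 to 7.6 ± 2.17 FPKM (-2.54 ± 0.21), and the oocyte genes Omt2b (-3.14 ± 0.59), Omt2a (-2.18 ± 0.44) and Oosp1 (-2.10 ± 0.35). Each of these 7 genes had an adjusted p between 1.3e-06 and 0.0066 in limma.

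In all, 4023 of 11730 tested genes (34.3%) changed, 2887 higher and 1136 lower in p150DN embryos (limma, Benjamini-Hochberg adjusted p below 0.05), and 1260 rose and 283 fell at least 2-fold. The 12 largest rises also held the aldo-keto reductase gene Akr1b8 (4.56), the endocytic receptor gene Lrp2 (4.48), the lipid desaturase gene Scd2 (4.30), Anxa2 (4.28), the arginine synthesis gene Ass1 (4.15), the apoptosis gene Pmaip1 (4.00), Hspb8 (3.78) and S100a11 (3.74). Mir5114 (5.28) was the largest of all, but it lies inside Scd2 and is shorter than 300 bases, so its reads cannot be separated from those of its host. The 12 largest falls further held Fkbp10 (-2.53), Inka1 (-2.17), Tspan4 (-2.12), Khdc1b (16.4 against 66 FPKM), the histone gene H2ac21 (-1.94), Trim61 (-1.93) and the short genes Mir700 (-2.51) and Mir3474 (-1.99), the last 2 of which are uncertain for their length. In 49.8% of the tested genes the 3 p150DN libraries did not overlap the 3 EGFP libraries, where chance gives 10%. The median of all tested genes was 0.19 on the log2 scale, against 0.06 after median-of-ratios scaling and -0.04 after quantile normalization, so list medians below are given also relative to all genes. With those scalings the split was 2261 higher and 1684 lower, and 1748 higher and 1827 lower. The count was 2238 without p150DN replicate 3 and 2560 without EGFP replicate 1. With both p150DN replicates 2 and 3 left out, an alternative chosen after seeing the data because they detected the most genes, it was 2314 (1301 higher, 1013 lower).

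Of the 30 trophectoderm genes tested, 19 rose, 2 fell and 9 did not pass the test, and adjusted over the list alone 19 rose and 3 fell. Their median log2 fold change was 1.21, or 1.02 above that of all genes (limma camera, adjusted p = 0.00134; adjusted p = 0.423 with an estimated correlation). Cdx2 and Gata3, transcription factors of the trophectoderm, rose from 3.06 ± 1.05 to 26.4 ± 9.97 FPKM (2.72 ± 0.29) and from 4.55 ± 1.81 to 47.8 ± 6.47 FPKM (3.17 ± 0.23; SD, n = 3 each). Ptges, a prostaglandin synthase gene (3.27 ± 0.25), rose as well. With p150DN replicates 2 and 3 left out the list median was 0.79 and its adjusted p 0.14, the highest of a range from 9.4e-06 over the alternatives at the preset correlation.

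Among 30 compaction, junction and polarity genes, 17 rose and 4 fell (adjusted over the list alone 17 and 4). Their median was 0.53, or 0.34 above all genes. Ezr, which encodes the membrane linker ezrin (3.29 ± 0.27), and the desmosome genes Pkp2 (3.02 ± 0.34) and Dsp (2.98 ± 0.32) led this list. Its camera test was near the threshold (adjusted p = 0.0472; adjusted p = 0.423 with an estimated correlation) and was lost in 7 of 21 alternatives, among them without EGFP replicate 1 (0.051), EGFP replicate 2 (0.053) or p150DN replicate 1 (0.061), over a range of 0.0021 to 0.078 in the alternatives. Of 21 primitive endoderm genes, 12 rose and 1 fell (adjusted over the list alone 13 and 1). The basement membrane collagen genes Col4a1 (2.51 ± 0.18) and Col4a2 (1.86 ± 0.19) and the endocytic adaptor gene Dab2 (2.00 ± 0.16) rose, and Gata4 was the member that fell. Gata6 was at 116 ± 25.7 FPKM in p150DN and 103 ± 38.8 FPKM in EGFP embryos (limma adjusted p = 0.59). The primitive endoderm list had a median of 0.64, or 0.45 above all genes (camera adjusted p = 0.031; adjusted p = 0.423 with an estimated correlation), and did not pass in 7 of 21 alternatives, among them without EGFP replicate 2 (0.052) or without p150DN replicate 1, 2 or 3 (0.054, 0.17 and 0.12), over a range of 0.0077 to 0.21.

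Inner cell mass and pluripotency genes did not move together: 8 of 25 rose, 4 fell and 13 did not pass (adjusted over the list alone 8 and 5; camera adjusted p = 0.629). Their median was -0.01 and their mean 0.22, which differ in sign. Tfcp2l1 (2.73 ± 0.41), Nanog (1.53 ± 0.34) and Sox2 (1.34 ± 0.25), transcription factors of pluripotent cells, rose. Nanog went from 23.4 ± 2.88 to 76.4 ± 35.6 FPKM and Sox2 from 0.184 ± 0.112 to 2.07 ± 0.848 FPKM. Pou5f1 was at 474 ± 75.7 against 317 ± 78.6 FPKM, a difference close to the threshold (0.59 ± 0.20, limma adjusted p = 0.046) that was lost in 9 of 20 alternatives, over a range of 0.0090 to 0.13.

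Targets of the tumour suppressor p53 rose in p150DN embryos: 24 of 32 were higher, 3 lower and 5 did not pass, or 25 and 3 adjusted over the list alone. The median was 1.49, or 1.30 above all genes (camera adjusted p = 3.7e-06; adjusted p = 0.266 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), rose from 27 ± 3.71 to 109 ± 39.2 FPKM (1.92 ± 0.23), and Mdm2, the ubiquitin ligase of p53, from 37.6 ± 2.55 to 88.7 ± 5.76 FPKM (1.22 ± 0.12; SD, n = 3 each). Pmaip1, which encodes the pro-apoptotic protein Noxa (4.00 ± 0.36), Btg2 (3.45 ± 0.26), Ccng1 (2.93 ± 0.16) and Phlda3 (2.82 ± 0.32) rose more. Of 22 immediate early and stress genes, 16 rose and 1 fell (adjusted over the list alone 16 and 1), among them the AP-1 genes Jun (2.87 ± 0.22) and Fosl1 (2.38 ± 0.48) and the immediate early gene Ier2 (2.25 ± 0.32). This list had a median of 1.07, or 0.87 above all genes (camera adjusted p = 0.000147; adjusted p = 0.423 with an estimated correlation). The 30 ATR and ATM damage response genes did not pass as a list (camera adjusted p = 0.0879, but 0.013 with no filter on low values, over a range of 0.013 to 0.42), with 3 higher and 6 lower, or 1 and 3 adjusted over the list alone. The repair gene Brca2 (-0.87 ± 0.15) and the checkpoint kinase gene Chek2 (-0.66 ± 0.14) were among those that fell.

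Of 47 nuclear genes of oxidative phosphorylation, 28 rose and 19 did not pass (31 rose adjusted over the list alone). The list median was 0.51, or 0.32 above all genes (camera adjusted p = 3.61e-05; adjusted p = 0.423 with an estimated correlation). Cox7b (1.40 ± 0.21), of the terminal oxidase, and Ndufa4 (0.99 ± 0.19) were examples. Of 19 glycolysis genes, 12 rose and 1 fell (14 and 2 adjusted over the list alone). Their median was 0.97, or 0.78 above all genes (camera adjusted p = 0.00231; adjusted p = 0.423 with an estimated correlation). They included the pyruvate kinase gene Pkm, from 7.37 ± 1.51 to 44.1 ± 10.4 FPKM (2.42 ± 0.20), and the glucose transporter genes Slc2a1 (2.31 ± 0.25) and Slc2a3 (2.13 ± 0.31). Also higher was Gapdh (2.57 ± 0.34), which was near the floor in EGFP embryos (0.411 ± 0.188 FPKM). In the cholesterol list 10 of 23 genes rose and 13 did not pass (13 rose and 1 fell adjusted over the list alone), led by Pmvk (1.75 ± 0.22), but the list did not pass camera (adjusted p = 0.0914), while it passed fry (adjusted p = 0.00589). Of 78 ribosomal protein genes 13 rose and 65 did not pass, while limma called 0 adjusted over the list alone, with 30 higher at an unadjusted p below 0.05. Their median was 0.23, or 0.04 above all genes. The camera call (adjusted p = 0.0174; adjusted p = 0.764 with an estimated correlation) was lost in 5 of 21 alternatives, among them median-of-ratios scaling (0.42), without EGFP replicate 2 (0.24) and without p150DN replicate 1 (0.088), over a range of 2.5e-07 to 0.42. It did not pass fry (adjusted p = 0.0857).

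The lists of histone, maternal and ribosome biogenesis genes passed camera as lower, though most of their members did not pass singly. By fry ribosome biogenesis genes passed (adjusted p = 0.0107), and histone and maternal genes did not (adjusted p = 0.13 and 0.0892). Of 28 core and linker histone genes, 9 fell, 1 rose and 18 did not pass, or 13 and 2 adjusted over the list alone. Their median was -0.51, or -0.70 relative to all genes (camera adjusted p = 9.62e-06; adjusted p = 0.423 with an estimated correlation). H2ac20 fell from 251 ± 17.6 to 112 ± 36 FPKM (-1.20 ± 0.20; SD, n = 3 each). The genes of the replacement histone H3.3 were at 135 ± 4.16 against 124 ± 8.81 FPKM for H3f3a (adjusted p = 0.41) and 248 ± 34.9 against 341 ± 60.2 FPKM for H3f3b (limma adjusted p = 0.054). The H3f3b difference (-0.45) passed in 11 of 21 alternatives, with adjusted p from 0.018 to 0.16. Histone genes have near-identical copies that share reads, so single members are uncertain, and the median of the list was -0.10 with p150DN replicates 2 and 3 left out (adjusted p = 0.21, over a range of 3.4e-09 to 0.21 in the alternatives). Of 38 maternal oocyte transcripts, 12 fell and 2 rose (14 and 2 adjusted over the list alone). The list median was -0.44, or -0.63 relative to all genes (camera adjusted p = 1.71e-07; adjusted p = 0.423 with an estimated correlation). The members that rose were Khdc3 (2.85 ± 0.25), of the subcortical maternal complex, and Uchl1 (1.32 ± 0.17), a ubiquitin hydrolase gene. Of 52 ribosome biogenesis genes, 15 fell and 37 did not pass, and 15 fell adjusted over the list alone. Wdr43 fell from 566 ± 32.1 to 286 ± 60.2 FPKM, and Imp3 (-1.20 ± 0.16) and Rrp12 (-0.80 ± 0.13) fell too. That list had a median of -0.27, or -0.46 relative to all genes (camera adjusted p = 1.71e-07; adjusted p = 0.423 with an estimated correlation).

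Imprinted genes passed the list test (10 of 21 rose, 1 fell, 11 and 1 adjusted over the list alone; median 0.66, or 0.47 above all genes; camera adjusted p = 0.031; adjusted p = 0.423 with an estimated correlation). Zdbf2 (1.74 ± 0.22) and Sfmbt2 (1.71 ± 0.20) rose, and the call was lost at a filter of 5 FPKM (0.40) and with p150DN replicates 2 and 3 left out (0.14), over a range of 0.013 to 0.40. Genes of the 2-cell stage did not pass as a list: 1 of 24 rose, 3 fell and 20 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.112). Obox6, a homeobox gene of early embryos, fell from 488 ± 37.3 to 211 ± 48.5 FPKM (-1.23 ± 0.16). The median of this list was 0.01, against -0.33 (adjusted p = 0.039, over a range of 0.0073 to 0.89) without p150DN replicate 2. Zscan4d, a marker of the 2-cell stage, was too low to test at 0.0972 ± 0.12 FPKM in p150DN and 0.716 ± 0.441 FPKM in EGFP embryos, and Zfp352 was at 4.26 ± 3.96 against 2.42 ± 1.93 FPKM (limma adjusted p = 0.63).

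The other lists did not pass camera in this comparison, and the p-values that follow are its adjusted values. Of 43 DNA replication genes, 11 rose and 6 fell (13 and 6 adjusted over the list alone; adjusted p = 0.824, but 0.00389 by fry), with Rpa1 (1.44 ± 0.17) and Rfc3 (1.23 ± 0.18) among those that rose. Of 35 G2 and mitosis genes, 8 rose and 9 fell (8 and 10 adjusted over the list alone; adjusted p = 0.0523). The list passed in 7 of 21 alternatives, among them without EGFP replicate 3 (0.035) and after median-of-ratios scaling (0.028), over a range of 0.0081 to 0.65. The condensin genes Ncaph (1.40 ± 0.22) and Ncapg (1.20 ± 0.19) rose and the kinetochore motor gene Cenpe (-1.27 ± 0.13) fell. Of 41 heterochromatin and DNA methylation genes, 12 rose and 5 fell (the same counts adjusted over the list alone; adjusted p = 0.426), with Tet2 (2.59 ± 0.33) and Dnmt3l (1.74 ± 0.27) higher and Smchd1 (-1.45 ± 0.25) lower. Of 25 germline genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone; adjusted p = 0.477). Those that rose included Tex19.1 (2.12 ± 0.26), Sycp3 (1.51 ± 0.16) and Zfp42 (1.29 ± 0.12), the last also a marker of pluripotent cells. The list median of -0.01 and its mean of 0.11 differ in sign. Of 15 CAF-1 and H3 chaperone genes, 5 rose, Chaf1a and Asf1a (1.04 ± 0.15) among them, and 3 fell (5 and 5 adjusted over the list alone; adjusted p = 0.824). Hira, an H3.3 chaperone gene, was at 29.1 ± 1.93 against 31.4 ± 2.69 FPKM (limma adjusted p = 0.56). Of 10 Hox and other lineage regulator genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.824), the latter being Foxa1 (-1.68 ± 0.31). Of 14 interferon response genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.816), with the antigen presentation genes Tap1 (2.05 ± 0.23) and H2-K1 (1.89 ± 0.18) higher and Stat2 (-1.49 ± 0.20) lower.

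Of the cumulus and granulosa, sperm and blood lists only 2, 2 and 1 genes were expressed enough to test, too few for a list test. Amhr2 fell from 19.8 ± 3.37 to 8.64 ± 3.45 FPKM, Odf2 rose from 8.22 ± 0.411 to 21.3 ± 3.07 FPKM, Dkkl1 rose from 1.83 ± 0.214 to 5.93 ± 1.45 FPKM, and Pecam1, at 11.1 ± 2.09 against 18.1 ± 2.15 FPKM, was lower (limma adjusted p = 0.019; SD, n = 3 each). Olfactory and vomeronasal receptor genes, 1481 of which were below 0.5 FPKM in both EGFP groups, were detected above 0 in 8.4%, 22.7% and 33.4% of cases in p150DN replicates 1, 2 and 3 and in 4.6% to 8.6% in the EGFP 8-cell libraries. Their mean stayed at or below 0.0588 FPKM in every library.

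**Figure D2:**
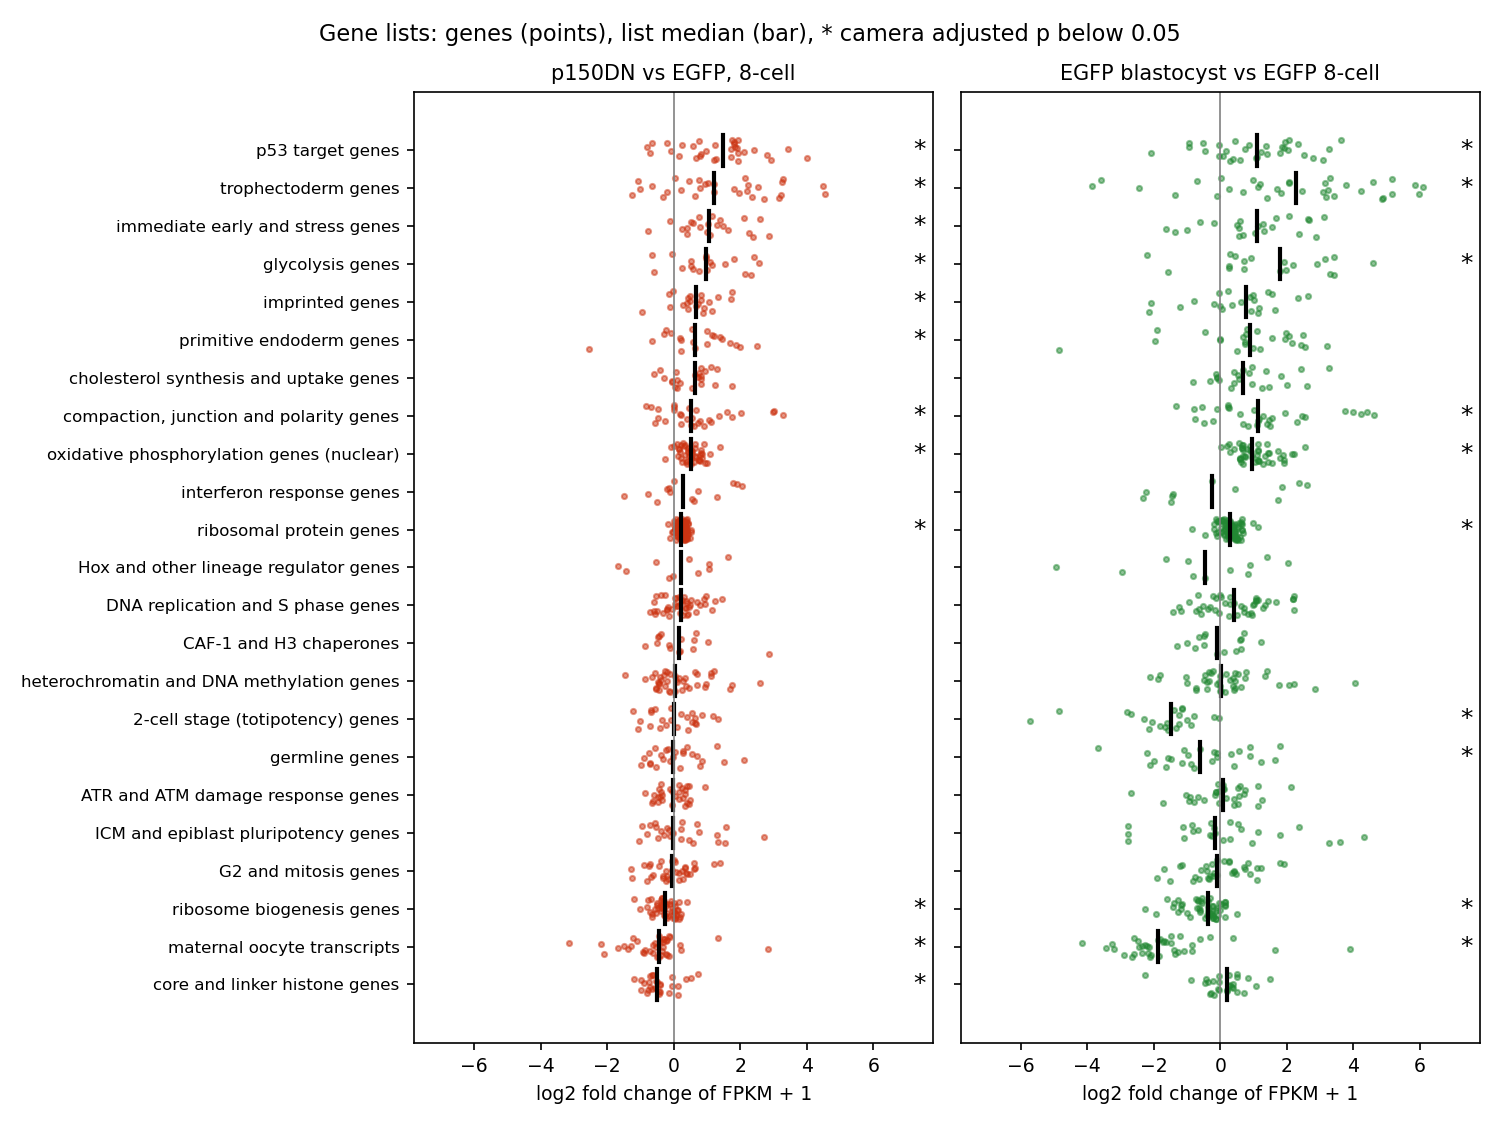
Log2 fold changes of FPKM + 1 for the genes of 23 lists (points) with the list median (bar), for p150DN against EGFP 8-cell embryos (left) and EGFP blastocysts against EGFP 8-cell embryos (right). Stars mark lists past camera at the preset correlation, 12 on the left and 10 on the right; p53 targets have the highest median on the left (1.49) and trophectoderm genes on the right (2.27).

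The second comparison, of EGFP blastocysts with EGFP 8-cell embryos, gives the change that control embryos undergo between these stages. Genes that rose included 25 of 34 of the trophectoderm, 21 of 31 of cell junctions, 43 of 47 of oxidative phosphorylation and 13 of 19 of glycolysis. Genes that fell included 19 of 22 of the 2-cell stage, 35 of 38 maternal transcripts and 28 of 52 of ribosome biogenesis. These 7 lists passed camera, and each call was lost with an estimated correlation (adjusted p = 0.168 to 0.189 with an estimated correlation). Krt18 rose from 5.98 ± 1.4 (SD, n = 3) to 427 ± 12.6 FPKM (SD, n = 2; log2 fold change 5.96 ± 0.18 SE), Cdx2 from 3.06 ± 1.05 to 115 ± 8.41 FPKM (4.87 ± 0.22) and Nanog from 23.4 ± 2.88 to 234 ± 7.68 FPKM (3.27 ± 0.13). Obox6 fell from 488 ± 37.3 to 16.2 ± 4.16 FPKM (-4.85 ± 0.16), and Klf17, another transcription factor gene of early embryos, from 123 ± 6.13 to 3.9 ± 0.676 FPKM (-4.66 ± 0.13). Each of these genes had an adjusted p between 1.1e-05 and 1.6e-05 in limma.

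Of 12199 tested genes 8236 changed (67.5%), 5198 higher and 3038 lower in blastocysts, and 2967 rose and 1557 fell at least 2-fold. The largest rises were Elf3 (6.49), Akr1b8 (6.14), Id2 (6.10), Krt18, Lrp2 (5.85), Scd2 (5.76), Ass1 (5.45), Anxa2 (5.41), Sdc4 (5.38) and Krt8 (5.16), with the short genes Mir5114 (6.94) and Mir147 (5.41) uncertain. The largest falls were Slc19a3 (-6.11), Tdpoz4 (-5.72), Socs3 (-5.51), Foxa1 (-4.94), Bex6 (-4.91), Obox6, Gata4 (-4.84), Trim43b (-4.77), Exoc3l2 (-4.70), Klf17 and Tmem229b (-4.62), with the short gene Mir1956 (-5.26) uncertain and listed at 0 in both blastocyst libraries. In 79.6% of the genes the groups did not overlap, where chance gives 20%. The median of all genes was 0.28, and the split was 4228 higher and 3796 lower after median-of-ratios scaling and 3997 and 3902 after quantile normalization. With 1 blastocyst library in the fit, assumed to vary like the EGFP 8-cell libraries, 5610 genes passed without blastocyst replicate 1 and 5459 without replicate 2.

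In the trophectoderm list 25 of 34 genes rose and 5 fell, also adjusted over the list alone. Their median was 2.27, or 1.99 above all genes (camera adjusted p = 0.00127; adjusted p = 0.189 with an estimated correlation); without blastocyst replicate 1 the adjusted p was 0.053, over a range from 4.8e-05. Gata3 reached 160 ± 17.7 FPKM (4.90 ± 0.25). In the junction list 21 of 31 rose and 5 fell, also adjusted over the list alone. The list median was 1.14, or 0.87 above all genes (camera adjusted p = 0.0194; adjusted p = 0.189 with an estimated correlation). Ezr (4.61 ± 0.22) and Dsp (4.41 ± 0.27) led it. Among oxidative phosphorylation genes 43 of 47 rose (44 adjusted over the list alone). Their median was 0.94, or 0.67 above all genes (camera adjusted p = 5.83e-08; adjusted p = 0.189 with an estimated correlation), for example Cox7b (2.55 ± 0.23). Of 19 glycolysis genes 13 rose and 2 fell, also adjusted over the list alone. The list median was 1.80, or 1.52 above all genes (camera adjusted p = 0.0198; adjusted p = 0.189 with an estimated correlation), for example Pkm (3.41 ± 0.18). Of 32 p53 targets 20 rose and 5 fell, also adjusted over the list alone. Their median was 1.09, or 0.81 above all genes; the call was marginal (camera adjusted p = 0.0479; adjusted p = 0.415 with an estimated correlation) and was lost without EGFP replicate 3 (0.083), without a trend (0.053) and with array weights (0.052), over a range of 0.0071 to 0.083, while the list passed fry (adjusted p = 0.00131). Ccng1 rose to 119 ± 8.98 FPKM (3.08 ± 0.18), Mdm2 to 57.5 ± 6.13 FPKM (0.60 ± 0.12), and Cdkn1a stood at 33.1 ± 1.66 FPKM in blastocysts (SD, n = 2) against 27 ± 3.71 FPKM (limma adjusted p = 0.11).

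Of 22 genes of the 2-cell stage, 19 fell and 3 did not pass, also adjusted over the list alone. The list median was -1.49, or -1.77 relative to all genes (camera adjusted p = 3.48e-08; adjusted p = 0.168 with an estimated correlation). Of 38 maternal transcripts 35 fell and 2 rose, also adjusted over the list alone. Their median was -1.86, or -2.13 relative to all genes (camera adjusted p = 1.9e-12; adjusted p = 0.189 with an estimated correlation). Btg4, a factor of maternal mRNA decay, fell by 3.42 on the log2 scale, and Khdc3 rose (3.90 ± 0.23). Of 52 ribosome biogenesis genes 28 fell and 1 rose, also adjusted over the list alone. The list median was -0.37, or -0.64 relative to all genes (camera adjusted p = 5.83e-08; adjusted p = 0.189 with an estimated correlation), Wdr43 (-2.25 ± 0.10) among them. Of 25 germline genes 13 fell and 5 rose, also adjusted over the list alone. Their median was -0.60, or -0.88 relative to all genes (camera adjusted p = 0.0195; adjusted p = 0.189 with an estimated correlation). Dmrtb1 (-3.67 ± 0.13) had the largest fall, and the call was lost at a filter of 5 FPKM (0.43, over a range from 0.014). Of 78 ribosomal protein genes 38 rose and 1 fell (34 and 1 adjusted over the list alone), but their median of 0.28 equalled that of all genes, and the camera call (adjusted p = 0.0495; adjusted p = 0.731 with an estimated correlation) was lost in 12 of 19 alternatives, over a range of 0.0053 to 0.80. It did not pass fry either (adjusted p = 0.0676).

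Of the lists that did not pass camera in the stage comparison, 7 passed fry, which does not compare a list with other genes. These were the lists of cholesterol (adjusted p = 0.000472), replication (0.00157), stress (0.00219), Hox and lineage (0.00365), imprinted (0.00672), primitive endoderm (0.00865) and heterochromatin genes (0.0149). The lists that did not pass camera held genes going both ways, with the same counts adjusted over the list alone except for histone genes (6 higher and 3 lower) and cholesterol genes (13 and 1). Inner cell mass genes had 10 higher and 8 lower of 25 (camera adjusted p = 0.468; median -0.17 and mean 0.21, which differ in sign), with Tfcp2l1 (4.31 ± 0.41) and Sox2 (3.59 ± 0.26) higher, Pou5f1 at 607 ± 25.9 against 317 ± 78.6 FPKM (0.96 ± 0.20) and Spic (-2.77 ± 0.14) lower. Core and linker histone genes had 7 higher and 3 lower of 28 (adjusted p = 0.666), with H4c1 (1.06 ± 0.25) higher and the oocyte linker histone gene H1f8 (-2.26 ± 0.17) lower. Primitive endoderm genes had 16 higher and 3 lower of 24 (adjusted p = 0.112, but 0.0081 with no filter on low values, over a range of 0.0081 to 0.70), with Dab2 (2.55 ± 0.18) higher and Gata4 lower. CAF-1 and chaperone genes had 6 higher and 7 lower of 15 (adjusted p = 0.326), with Asf1a (1.24 ± 0.17) higher and Hira (-0.75 ± 0.13) lower, and Chaf1b at 21.9 ± 1.98 FPKM (SD, n = 2; limma adjusted p = 0.52). H3f3a and H3f3b were at 110 ± 1.81 and 272 ± 11.4 FPKM in blastocysts (limma adjusted p = 0.16 and 0.11), and Gata6 at 140 ± 3.39 FPKM (0.18). These passed in 3, 5 and 1 of 19 alternatives, over ranges of 0.0090 to 0.42, 0.016 to 0.30 and 0.027 to 0.48. Replication genes had 22 higher and 10 lower of 43 (adjusted p = 0.422), with Lig1 (2.20 ± 0.12) higher, and mitosis genes 13 and 13 of 35 (adjusted p = 0.236). Damage response genes had 11 higher and 8 lower of 30 (adjusted p = 0.468), with Brca2 (-2.68 ± 0.12) lower. Cholesterol genes had 14 higher and 1 lower of 23 (adjusted p = 0.0991, 0.029 with no filter and 0.036 without blastocyst replicate 2, over a range of 0.029 to 0.12), with Srebf2 (3.26 ± 0.17) higher. Stress genes had 16 higher and 4 lower of 22 (adjusted p = 0.102, but past the threshold in 3 of 19 alternatives, 0.033 without blastocyst replicate 1 the lowest, over a range of 0.033 to 0.12), with Jun (2.87 ± 0.18) higher. Hox and lineage genes had 4 higher and 6 lower of 11 (adjusted p = 0.211, and 0.033 and 0.036 without blastocyst replicate 1 or 2, over a range of 0.033 to 0.37). Imprinted genes had 12 higher and 4 lower of 22 (adjusted p = 0.422), with Igf2r (-2.15 ± 0.26) lower, and interferon genes 4 and 5 of 11 (adjusted p = 0.422). Heterochromatin genes had 12 higher and 11 lower of 41 (adjusted p = 0.592), with Tet2 (4.05 ± 0.15) higher. Amhr2 (-3.09 ± 0.18) and Pecam1 (-1.46 ± 0.26) fell and Odf2 (1.81 ± 0.13) and Dkkl1 (2.84 ± 0.21) rose, the same directions as in p150DN embryos.

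The last comparison asked whether the p150DN change runs along the change between the stages. In most genes it did. Of 2802 genes higher in p150DN embryos and tested in both comparisons, 2541 were also higher in blastocysts (1133 for independent lists), Krt18, Elf3, Cdx2 and Gata3 among them, and of 1136 lower genes 1035 were also lower (297 for independent lists), Gata4, Obox6 and Wdr43 among them. The values for independent lists leave out that the comparisons share their controls. A further 17 genes rose in p150DN embryos and fell in blastocysts. Chaf1a stood apart, with 2.86 in p150DN embryos and -0.10 in blastocysts, as did Cdkn1a with 1.92 and 0.29. Across 11487 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.836 and Spearman's rho of 0.830, and 83.7% had the same sign. Both comparisons use the same 3 EGFP 8-cell libraries, and 100 simulations of unchanged groups against them gave a mean r of 0.455 (highest 0.485), a mean rho of 0.442 and 66.3% of the same sign. The covariance was 0.681 observed and 0.027 simulated, a difference of 0.654. With 1 EGFP library used for the p150DN comparison and the other two for the stage comparison, so that no control was shared, r was 0.788, 0.758 and 0.757 and the covariance 0.679, 0.684 and 0.631. In these splits 607 of 653, 739 of 808 and 421 of 446 higher genes were shared (245, 339 and 181 for independent lists), and 116 of 120, 222 of 234 and 55 of 58 lower genes (28, 59 and 15). The covariance thus stayed near 0.681 with no control shared, which argues against the shared controls as its main source. The lower r of the splits cannot be assigned, because a single EGFP library in 1 part is too few for a full split. Part of r with all controls may therefore come from the shared controls. The overlaps did not shrink in the splits, with 93%, 91.5% and 94.4% of higher genes shared against 90.7% with all controls. Of lower genes 96.7%, 94.9% and 94.8% were shared, against 91.1%. Fewer genes were called in the splits, so these shares do not exclude such a part in the overlaps. The slope of the p150DN change on the stage change was 0.483.

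**Figure D3:**
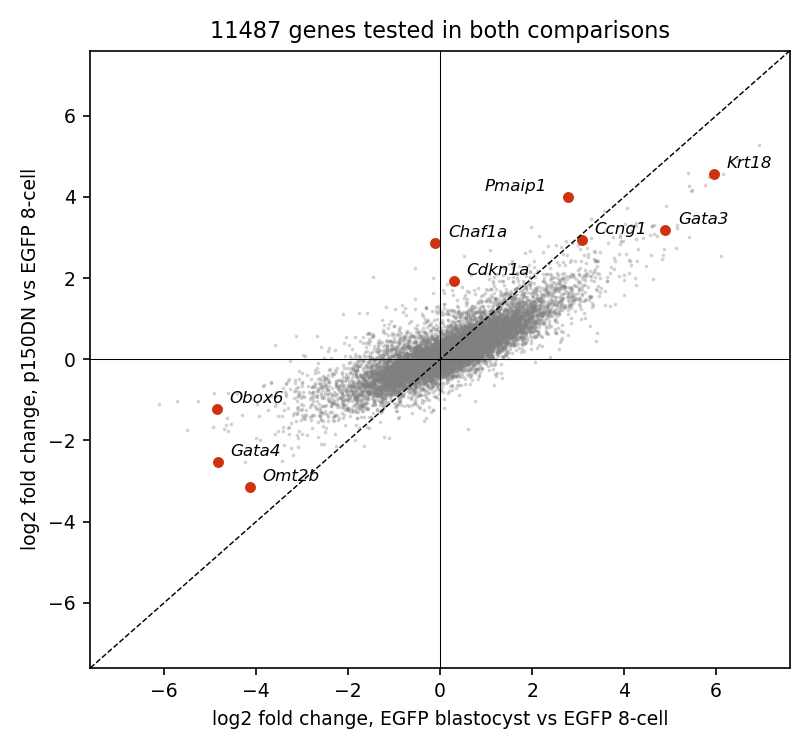
Log2 fold change of FPKM + 1 in p150DN against EGFP 8-cell embryos (vertical) over that in EGFP blastocysts against EGFP 8-cell embryos (horizontal), 1 point per gene for 11487 genes, with the line of equal change dashed. Most genes lie along a shallower slope than the dashed line (r 0.836, slope 0.483), and Chaf1a and Cdkn1a lie above the cloud.

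Principal components were computed over the 8 libraries. The first (67.8% of the variance) had the EGFP 8-cell libraries at -60.7, -62.7 and -55.1, the blastocyst libraries at 73.8 and 75.8, and the p150DN libraries at 14.7, -2.5 and 16.6. On the second (13.9%) the p150DN libraries lay lowest, at -6.3, -42.6 and -35.2 for replicates 1, 2 and 3. Replicate 1 was nearer to the EGFP 8-cell libraries (12.7 to 16.3) than to replicates 2 and 3. Those 2 replicates also had the most detected genes, so this component cannot be read as treatment alone.

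**Figure D4:**
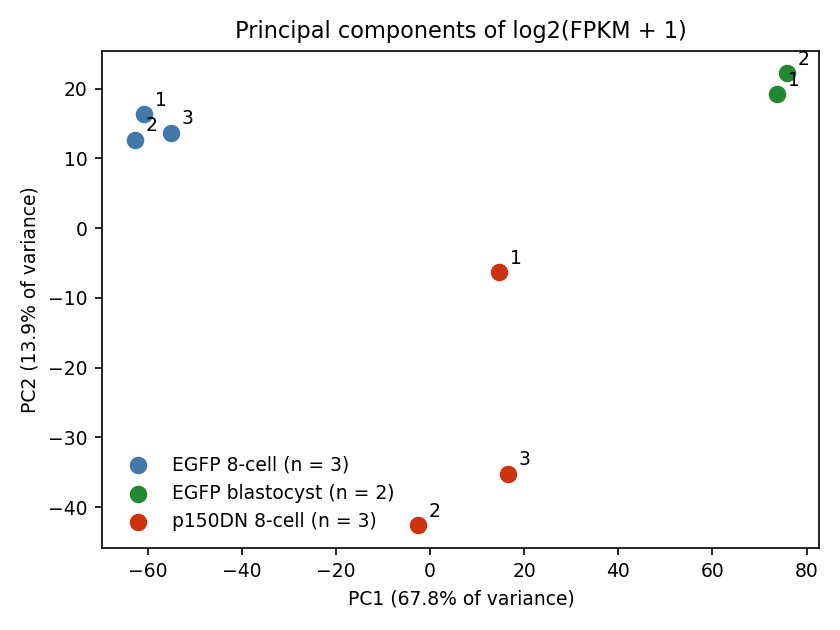
The 8 libraries on the first and second principal components of log2(FPKM + 1), with 67.8% and 13.9% of the variance, points coloured by group and numbered by replicate. The p150DN libraries lie between the EGFP groups on the first component and below both on the second.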

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

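Of the alternatives, limma voom, the limit of 300 bases, the removal of p150DN replicates 2 and 3 together and TPM scaling for the correlation were chosen after seeing the data, the last before any correlation was computed. No alternative called a gene in the direction opposite to the reported one. Of 118 called genes of the p150DN comparison chosen by the naming rule, 93 kept their call in every setting that tested them. A further 25 lost it in some setting. In the stage comparison 112 of 117 kept it. Some genes were not tested in every setting, Sox2 for example in 16 of 21 for p150DN. For p150DN against EGFP 8-cell embryos (4023 genes, 2887 higher and 1136 lower), a filter at 5 FPKM left 1812 higher, with fewer genes tested. Quantile normalization gave 1748 higher and 1827 lower. The higher share of changed genes fell with the median log2 fold change of all genes. It was 71.8% at a median of 0.19 (as deposited), 64.6% at 0.13 (TPM), 57.3% at 0.06 (median of ratios) and 48.9% at -0.04 (quantiles). The surplus of higher genes thus depends on the scaling, and which scaling is right was not tested. Leaving out 1 library gave 2238 to 3553 changed, 1488 to 2318 higher and 665 to 1261 lower, with fewer samples, the lowest counts without p150DN replicate 3 (2238 changed) and EGFP replicate 1 (2560 changed, 665 lower). Without p150DN replicates 2 and 3, which leaves 1 library assumed to vary like the EGFP libraries, 2314 changed and 1301 were higher. The stage comparison gave 5459 to 8144 changed and 3150 to 5216 higher with 1 library left out, lowest without blastocyst replicate 2. Limma voom called 4111 and 8307 genes, and array weights 5399 and 8751.

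With an estimated correlation, camera called 0 of 23 lists in the p150DN comparison (12 at the preset correlation, 11 with fry, 1 at an unadjusted p below 0.05) and 0 of 23 between stages (10 at the preset correlation, 16 with fry, 5 at an unadjusted p below 0.05). The lowest adjusted p was 0.266 and 0.168. The median of the 2-cell list in the p150DN comparison (0.01) turned to -0.04 with no filter (adjusted p = 0.0073), ranged from -0.33 (without p150DN replicate 2, adjusted p = 0.039) to 0.41 (without p150DN replicate 1) and was -0.78 without p150DN replicates 2 and 3 (adjusted p = 0.012), with adjusted p from 0.0073 to 0.89 over all alternatives and a cause that was not tested. The correlation between the comparisons was 0.757 to 0.865 over the alternatives, and 0.841, 0.672 and 0.805 with p150DN replicate 1, 2 or 3 alone.

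With the replicate number as a block (replicate block), 4081 genes changed between p150DN and EGFP 8-cell embryos (2878 higher, 1203 lower) and 7861 between stages. Deviations of same-numbered libraries correlated by 0.062, 0.099 and 0.035, and EGFP replicate 3 correlated best with p150DN replicate 1 (0.078), so the numbers were not taken to pair the libraries. Depth limits the weakest genes: at 1 FPKM a gene of 300 bases rests on a few fragments per library.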

Other observations

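The comparison of p150DN 8-cell embryos with EGFP blastocysts, the set of replication-dependent histone genes and the tests of collection time, depth and the normal change of p53 targets were chosen after the results were seen. In p150DN embryos 134 of 11583 genes lay above both EGFP 8-cell embryos and blastocysts, 26 below both and 1342 between them (limma). After Chaf1a, the genes above both included p53 targets, 8 of 32 in that list (Fisher's exact test, p = 2.2e-09, over genes that are not independent). Of these 32 genes 24 were already higher than in EGFP 8-cell embryos, which being above both requires. The test was set against all compared genes, so its p partly repeats that result. Against blastocysts Cdkn1a was higher by a log2 fold change of 1.63 ± 0.26 (SE; adjusted p = 0.0083), Pmaip1 by 1.21 ± 0.34 and Bbc3, which encodes the pro-apoptotic protein Puma, by 0.90 ± 0.16. Ei24, also of that list, was higher than in blastocysts (1.37 ± 0.17) but fell against EGFP 8-cell embryos (-0.72 ± 0.17), so that it lay between the stages. The list had 9 of 32 genes higher and 23 that did not pass (median 0.30; camera adjusted p = 0.019; adjusted p = 0.48 with an estimated correlation), and the camera call was lost with no filter on low values (adjusted p = 0.062, the highest over the alternatives at the preset correlation, from 0.0076). With 1 blastocyst library left out the test called far fewer genes, and 2 (without replicate 1) or 0 (without replicate 2; 17 genes above both in all, limma) of the 32 lay above both stages. Without p150DN replicate 1, 2 or 3, 246, 59 and 49 genes lay above both, 9, 3 and 3 of them p53 targets. Fisher's exact test, with the same limit, gave p = 2.3e-08, 0.00073 and 0.00042. Against the 3301 genes that differed between p150DN embryos and blastocysts with all libraries, 501 and 323 did so without blastocyst replicate 1 or 2. Genes of the 2-cell stage (14 of 23 higher; median 1.75; camera adjusted p = 7.4e-10; adjusted p = 0.48 with an estimated correlation) and maternal transcripts (24 of 37 higher, 2 lower; median 1.31; camera adjusted p = 4.1e-10; adjusted p = 0.6 with an estimated correlation) were still above their blastocyst level.

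Many replication-dependent histone genes went the other way. Of 55 such genes 30 fell against EGFP 8-cell embryos (median -0.74) and 22 against blastocysts (median -0.67). The rest did not pass, and 0 rose. Between the stages 8 rose and 11 fell (median -0.06). In the core and linker histone list fixed beforehand, 10 of 28 genes were lower than in blastocysts and 1 higher. That list passed camera (adjusted p = 0.0011), but not with an estimated correlation (adjusted p = 0.68) or by fry (adjusted p = 0.16). The replication-dependent genes made up 13 of the 26 genes below both stages, a share with no test, since the set was chosen from these values and its genes share reads. Among them were H1f5, H1f3, H3c8 and H2ac18. Without either blastocyst library limma called 0 genes of any kind below both stages. Without p150DN replicate 1, 2 or 3 these genes made up 32 of 59, 7 of 17 and 6 of 13, and without EGFP 8-cell replicate 1 they made up 7 of 15. Other scalings gave 15 to 40 genes below both, 8 to 13 of them histone genes. Against the mean of all EGFP 8-cell libraries their median was -0.37, -0.76 and -1.08 in p150DN replicates 1, 2 and 3. It was -0.12 and -0.01 in the blastocyst replicates. Each EGFP 8-cell replicate was set against the mean of the other EGFP 8-cell libraries only, which gave 0.19, -0.39 and 0.14. That reference enlarges the EGFP values, so for these 55 genes they do not show whether p150DN replicate 1, the least changed, lay within the EGFP range. In the core and linker histone list it did by the median, 74.3 FPKM against 84.1, 67.5 and 85.2 FPKM in EGFP 8-cell replicates 1, 2 and 3. Its mean, 135 FPKM, was just below theirs (157, 136 and 161 FPKM). The list medians of p150DN replicates 2 and 3, 51.9 and 42.2 FPKM, lay below the EGFP range. No explanation of this pattern was tested.

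The first pattern is that the p150DN libraries lay between the stages. Blastocyst RNA mixed into them would move rising and falling genes by the same fraction of the way. The fraction was larger in falling genes, by 0.223, 0.115 and 0.135 in replicates 1, 2 and 3, which argues against mixing as the whole cause. The 95% bootstrap intervals, from 0.088 upwards, came from resampled genes, which are not independent. That of replicate 2 (0.088 to 0.143) reached below the difference set beforehand for arguing against mixing. Over 4 other scalings the lowest r was 0.82, with quantile normalization, against 0.836. The others shift the genes of a library nearly alike, so they could hardly move r and cannot decide about the scaling. The argument against the scaling as the cause thus rests on quantile normalization alone. A later collection time of the p150DN embryos cannot be told apart from an effect of p150DN, because the labels of 0 of the 8 libraries give a collection time. An effect of p150DN, which the design names, stays open and was not tested apart from collection time.

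The second pattern is that more genes were detected at a low level in p150DN libraries. Deeper sequencing does not account for it, because after thinning every library to the same depth 19916 ± 1565 (SD, n = 3) genes were detected in p150DN and 17558 ± 586 (SD, n = 3) in EGFP 8-cell libraries, a gain of 2358, and p150DN replicate 3, with the fewest fragments, had the most. The gain was carried by p150DN replicates 2 and 3 (20264 and 21278 genes), as replicate 1 (18206) lay below EGFP replicate 3 (18225). Background reads such as those of genomic DNA remain open: olfactory and vomeronasal receptor genes, which embryos should not express, gained in mean FPKM 0.28 of the mean gain of all low genes, with ratios of 0.105, 0.252 and 0.336 in replicates 1, 2 and 3. That lies between the values that background alone and its absence would give, so background may explain part of the gain, and the biological alternative, a wider low-level transcription in p150DN embryos, cannot be told apart from it.

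The third pattern is the higher level of p53 targets. It was not the work of a single p150DN library, since the list median against the EGFP 8-cell mean was 1.34, 1.24 and 1.34 in replicates 1, 2 and 3. Whether it was only the normal change between the stages stays open for the list. Its median was 0.3 above the blastocyst level, but 23 of 32 members did not pass and 1 of the 9 that did was Ei24. The camera call was lost with no filter. It was also lost with an estimated correlation (camera adjusted p = 0.48), but that loss can hardly decide the question. Maternal transcripts, with 24 of 37 higher than in blastocysts, did not pass that test either (camera adjusted p = 0.6). An effect of p150DN, which the design names, and damage from handling that differed between the groups both stay open, as no test here separates them.

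For the number of genes that differed between p150DN and EGFP 8-cell embryos, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4023 genes (5353 at an unadjusted p below 0.05) and was the only 1 of the 10 with as many. The highest of the other splits gave 0 (limma; at most 463 at an unadjusted p below 0.05).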
